A study of Mus musculus with 12 samples.

How the data were processed

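Sorted skin cells of untreated C57BL/6 mice were profiled on 12 microarrays, 3 for each of 4 groups: MHC-II-negative melanophages, MHC-II-positive melanophages, MHC-II-negative macrophages and MHC-II-positive macrophages. Melanophages are macrophages laden with melanin. According to the labels, all cells were CD11b-positive, CD24-negative, CD64-positive, CCR2-negative and Ly6C-negative, and melanophages had a high side scatter (SSC-A). For the macrophages the labels disagree, since the titles give a high side scatter and the phenotype field a low one, so side scatter was not used to define a group. Total RNA was extracted with a Qiagen RNeasy Plus Micro kit, 3 to 20 ng of it was amplified with the NuGEN Ovation Pico WTA system, and the product was labelled with biotin, per the labels' protocols. The arrays follow Affymetrix protocols, per the labels.

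The deposited value table holds log2 expression values made by the authors with RMA (robust multi-array average) in the R package oligo, per the submitters' processing notes. Versions, the settings of RMA and any filter are not given in the sources used here. Array medians over all probe sets of the table lay between 2.97 and 3.08. Where the lower of 2 group means lay near them, the log2 difference and fold are lower bounds. This is marked below for Cd207, Ccl22 and Chil3 and was not marked for every gene. The lowest group mean of a sort marker was 3.16, so differences of sort markers may be lower bounds too. The table has 35556 probe sets with no missing values, no pair of arrays among 66 holds identical values, and no column belongs to another sample. Of the probe sets, 21789 carry 1 gene symbol in the platform annotation, 1621 carry several and 12146 have none here. Symbols were checked through the Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, which held 21698 of those identifiers and lacked 91, and no symbol needed an update. No genome build is named for the array values, so no coordinates are given.

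For each gene the probe set with the highest mean over all 12 arrays was kept, which left 19938 genes, 999 of them with more than 1 probe set. No filter on dim genes was used in the main setting. The values were fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with a mean per group and all 12 arrays in 1 fit (8 residual and 2.44 prior degrees of freedom). 7 comparisons were tested: melanophages against macrophages averaged over both MHC-II classes and within each class, MHC-II-positive against MHC-II-negative cells averaged over both cell kinds and within each kind, and the interaction. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Errors of log2 differences are standard errors (SE) of the fit. Nothing in the labels says that the 3 arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

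The comparisons, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for both averaged comparisons, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose arrays do not overlap in the same direction within both strata. Within a stratum and for the interaction it takes 5 in each direction. Predicted genes, clone names, olfactory and vomeronasal receptors and antigen receptor segments are left out. Every sort marker is named, and of each list up to 4 called members with the largest change or, where none passed, the member with the smallest adjusted p. Of 33 gene lists with 574 entries, 506 entries were matched to a gene tested here. 1 list (mitochondrially encoded genes) had no matched member, and 32 lists were tested with limma's camera with a preset correlation between genes of 0.01 (Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation and the rotation test fry were alternatives. Genes not matched to a probe set with 1 symbol, among them the Ly6C genes of the gate, were not analysed here.

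The fit was tested on simulated data made from the spread of these arrays, with 100 genes changed by 1 and 100 by 2 on the log2 scale among 19938. The changed genes were drawn from the brighter 50% of genes, so recovery of dim genes was not tested. Noise was drawn independently for each gene, so deviations that many genes of an array share were left out. For melanophages against macrophages averaged over MHC-II the fit called 74% of the smaller and 97% of the larger changes with 7 false calls. For the averaged MHC-II comparison it called 76% and 96% with 11 false calls, and for the interaction 40% and 67% with 3 false calls.

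Alternatives were 2 filters on dim genes, quantile normalization again, cyclic loess, centring on array medians, every probe set of the table, the mean of all probe sets of a gene, limma with trend, robust or array weights, fits of the arrays of 2 groups only, and leaving out each array in turn. The sample codes in the titles fall into 3 runs of 4 consecutive numbers, with 1 array of each group per run. No label says that a run shares a day or a sort, so the run entered only as an alternative, as a fixed or a random block. After the data were seen, a fit without the 2 arrays farthest from their group mates was added, the named calls were also read from the fits of every probe set and of 2 groups only, and the lists holding the MHC-II chains were tested without them.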

Results

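Gene expression was measured in pigment-laden macrophages (melanophages) and other macrophages sorted from the skin of untreated C57BL/6 mice. Each cell kind was split into an MHC-II-negative and an MHC-II-positive gate, and each of the 4 groups had 3 arrays. The design allows the cell kinds to be compared within each MHC-II class, the MHC-II classes within each cell kind, and both differences with each other. Log2 expression values of 19938 genes were compared. The mean correlation of an array with its group mates ranged from 0.972 to 0.988, and the leading 3 principal components held 24%, 16.9% and 10.8% of the variance.

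Ctsk, a lysosomal cysteine protease best known from osteoclasts, was 4.98-fold higher in melanophages than in macrophages, averaged over MHC-II class (log2 difference 2.32 ± 0.25 SE, adjusted p = 0.0167). Its mean log2 value was 9.73 ± 0.21 in MHC-II-negative and 9.06 ± 0.30 in MHC-II-positive melanophages, against 7.47 ± 0.38 and 6.68 ± 0.85 in the corresponding macrophages (SD, n = 3). Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, was 5.10-fold higher (2.35 ± 0.32, adjusted p = 0.0323). Gpnmb, a glycoprotein of melanosomes and lysosomes that macrophages also make, was 4.31-fold higher (2.11 ± 0.32, adjusted p = 0.0439). In the opposite direction, Lyve1, a hyaluronan receptor of lymphatic endothelium and of some resident macrophages, was 7.23-fold lower in melanophages (-2.85 ± 0.35, adjusted p = 0.021). Retnla, a secreted product of alternatively activated macrophages, was 5.62-fold lower (-2.49 ± 0.20, adjusted p = 0.00221).

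**Figure D1:**
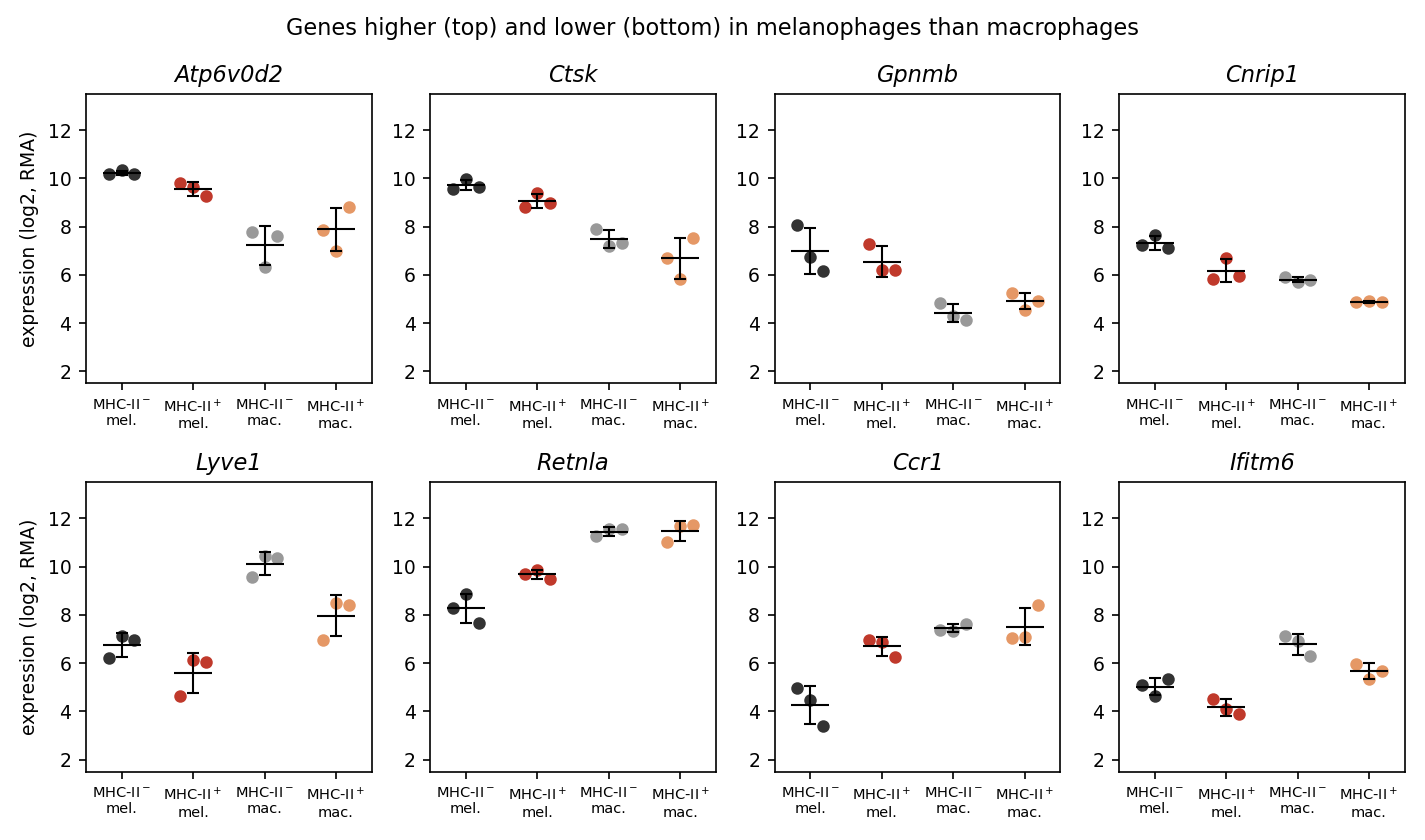
Expression (log2, RMA) of the 4 leading rises (top) and 4 leading falls (bottom) by the rule for named genes in melanophages (mel.) against macrophages (mac.), by MHC-II class. Points are single arrays (n = 3 per group), long bars group means and error bars SD; Ctsk averaged 9.73 in MHC-II-negative melanophages and 7.47 in MHC-II-negative macrophages.

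In all, 24 genes differed between the cell kinds when averaged over MHC-II class, 11 higher and 13 lower in melanophages. At least 2-fold differences made up 5 of the rises and 9 of the falls. Other genes higher in melanophages were Cnrip1, which encodes a cannabinoid receptor interacting protein (1.41 ± 0.15), and the glutathione transferases Gstm1 (0.97 ± 0.14) and Gstm3 (0.70 ± 0.10). So were the C-type lectin Clec4d (0.81 ± 0.12), the pore-forming Mpeg1 (0.73 ± 0.11) and Naa20 (0.82 ± 0.11). The genes lower in melanophages included the chemokine receptors Ccr1 (-2.00 ± 0.30) and Cx3cr1 (-1.54 ± 0.23), the chemokine Ppbp (-1.33 ± 0.15), the metalloelastase Mmp12 (-1.46 ± 0.22), the adhesion receptor Adgre5 (-1.56 ± 0.23) and Ifitm6 (-1.63 ± 0.19). Also lower were Syngr2 (-0.92 ± 0.14), the glucose transporter Slc2a1 (-0.87 ± 0.10), the langerin gene Cd207 (-1.16 ± 0.15) and the integrin Itgax, which encodes CD11c (-0.80 ± 0.11). Cd207 lay near the array medians in all groups but MHC-II-positive macrophages, so its difference was read as a lower bound. An unadjusted p under 0.05 was found for 1500 genes, where chance gives 997. Arrays of the cell kinds did not overlap, in the same direction in both MHC-II classes, for 141 genes higher and 91 lower in melanophages, where chance gives 0.25% of genes (49.8) per direction.

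The number of genes called between the cell kinds depended on single arrays. It fell from 24 to 1 without MHC-II-negative melanophages replicate 1 and to 1 without MHC-II-negative macrophages replicate 2. It was 7 and 10 without MHC-II-negative melanophages replicates 2 and 3, 11 and 10 without MHC-II-positive melanophages replicates 2 and 3, 12 without MHC-II-negative macrophages replicate 3 and 10 without MHC-II-positive macrophages replicate 2. Of the 21 named calls, only Retnla passed in all 24 alternatives, with a highest adjusted p of 0.0166. In the fit of every probe set, not among those 24 for single genes, Retnla passed (adjusted p = 0.00789) and the other 20 did not, among them Ctsk (0.0503) and Gpnmb (0.0887). Of the 24, Ctsk, Cnrip1, Ppbp and Ifitm6 missed the threshold in the fits without MHC-II-negative melanophages replicate 1 (adjusted p = 0.0543) and MHC-II-negative macrophages replicate 2 (adjusted p = 0.0681). Gpnmb missed it in 11 of the 12 leave-one-out fits (highest adjusted p over all alternatives 0.136). MHC-II-negative macrophages replicate 1 and MHC-II-positive macrophages replicate 3 stood farthest from their group mates, with SDs of the difference of 0.406 and 0.356. Without both, 117 genes were called, 38 higher and 79 lower.

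Of 32 gene lists, 7 were lower in melanophages with camera and 0 higher. Of the 23 genes of resident and alternatively activated macrophages, Lyve1 and Retnla fell, 0 rose and 21 did not pass, and 8 were lower when adjusted over the list alone. The list was lower as a set (adjusted p = 4.13e-09, and adjusted p = 0.148 with an estimated correlation). With limma 0 of the 22 immediate early and heat shock genes passed (8 with unadjusted p under 0.05), with 5 lower adjusted over the list alone, but 21 of the 22 log2 differences lay below 0 (adjusted p = 1.16e-10, and adjusted p = 0.148 with an estimated correlation). The smallest gene-level adjusted p of that list belonged to the chaperone Hspa1a (-0.54 ± 0.12, adjusted p = 0.172). Of 17 dendritic cell genes, Cd207 and Itgax fell, and 3 were lower adjusted over the list alone (adjusted p = 0.00105, and adjusted p = 0.139 with an estimated correlation). Of 17 glycolysis and hypoxia genes, Slc2a1 fell, and 1 was lower adjusted over the list alone (adjusted p = 0.0219, and adjusted p = 0.155 with an estimated correlation). Of 22 scavenger and phagocytic receptors 0 passed with limma (7 with unadjusted p under 0.05), with 2 higher and 5 lower adjusted over the list alone (adjusted p = 0.00192, and adjusted p = 0.156 with an estimated correlation). Of 14 genes of MHC class II antigen presentation 0 passed with limma (4 with unadjusted p under 0.05), with 2 lower adjusted over the list alone (adjusted p = 0.00335, and adjusted p = 0.148 with an estimated correlation).

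The genes of the sort markers were the list whose lower level in melanophages also passed with an estimated correlation (adjusted p = 4.13e-09, and adjusted p = 0.00672 with an estimated correlation). With limma 0 of its 7 measured members passed over all genes (6 with unadjusted p under 0.05), and 6 were lower adjusted over the list alone. Itgam, which encodes CD11b, differed by -1.02 ± 0.18 (adjusted p = 0.0772), Cd24a by -1.28 ± 0.32 (adjusted p = 0.266), H2-Eb1 by -0.69 ± 0.18 (adjusted p = 0.305), H2-Ab1 by -0.65 ± 0.22, Ccr2 by -0.48 ± 0.20, Fcgr1 by -0.45 ± 0.16 and H2-Aa by -0.37 ± 0.24.

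The list of lysosomal genes did not pass between the cell kinds, averaged over MHC-II class. Of 34 lysosomal genes, Ctsk and Atp6v0d2 rose, 0 fell and 32 did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.16). Of 16 genes of lipid-associated macrophages, Gpnmb rose and Itgax fell, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0724). Among 15 core macrophage genes Cx3cr1 fell, with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.0636). Among 17 targets of the oxidative stress regulator NRF2 Gstm1 rose, with 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.541). Of the 18 melanocyte and pigment genes 0 passed with limma over all genes and 0 adjusted over the list alone (3 with unadjusted p under 0.05; camera adjusted p = 0.507); 13 of the 18 were dimmer than the median gene. Lists of cholesterol synthesis (adjusted p = 0.134), cholesterol efflux (0.557), iron handling (0.745), complement (0.134), inflammatory cytokines (0.732), interferon-stimulated genes (0.16), cell cycle (0.0588) and ribosomal proteins (0.0724) did not pass. Of the lists for other cell types, monocytes (0.696), keratinocytes (0.16), hair follicle (0.745), fibroblasts (0.541), endothelium (0.534), T cells and ILC (0.732), B cells (0.577), mast cells (0.745), neutrophils (0.622), Schwann cells (0.534), skeletal muscle (0.557) and pericytes (0.732) did not pass. The fall of Lyve1 is counted in the endothelial list as well. Median and mean differed in sign for cholesterol efflux, iron handling, inflammatory cytokines, endothelium, T cells, B cells, mast cells and neutrophils.

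List calls between the cell kinds also depended on single arrays. The call of glycolysis and hypoxia ended without MHC-II-negative melanophages replicate 3 (adjusted p = 0.16), MHC-II-negative macrophages replicate 3 (0.185) or MHC-II-positive macrophages replicate 3 (0.056). It ended in the 2 filters on dim genes as well (0.0838 and 0.0784). That of MHC class II antigen presentation ended without MHC-II-positive macrophages replicate 3 (0.0551). Among the lists that did not pass, lysosomal genes were called without MHC-II-negative melanophages replicate 2 (0.047) or MHC-II-negative macrophages replicate 3 (0.0156). Cell cycle genes were called in 7 of 21 alternatives, among them the fits without MHC-II-positive macrophages replicate 1 (0.00743), MHC-II-negative melanophages replicate 2 (0.0254), MHC-II-positive melanophages replicate 2 (0.0468) and MHC-II-positive melanophages replicate 3 (0.0079). Ribosomal proteins were called in 4, namely with cyclic loess (0.0111) and without MHC-II-negative melanophages replicate 1 (0.0359), MHC-II-negative melanophages replicate 2 (0.0254) or MHC-II-negative macrophages replicate 2 (0.0353). Core macrophage genes were called without MHC-II-negative melanophages replicate 1 (0.0318), MHC-II-negative melanophages replicate 2 (0.018), MHC-II-positive melanophages replicate 2 (0.0389) or MHC-II-negative macrophages replicate 1 (0.0205). Lipid-associated macrophage genes were called without MHC-II-negative melanophages replicate 3 (0.046) or MHC-II-positive melanophages replicate 3 (0.0273). Cholesterol synthesis was called without MHC-II-negative melanophages replicate 2 (0.047), MHC-II-negative macrophages replicate 2 (0.00829) or MHC-II-positive macrophages replicate 2 (0.0376). Complement was called without MHC-II-negative melanophages replicate 2 (0.047), and keratinocyte genes without MHC-II-positive melanophages replicate 1 (0.0351). Interferon-stimulated genes were called without MHC-II-positive macrophages replicate 1 (0.0422) or MHC-II-positive melanophages replicate 2 (0.0468). Not all of these gained calls are falls. In the fit without both far macrophage arrays, cell cycle, lipid-associated macrophage, cholesterol synthesis and keratinocyte genes lay higher in melanophages. Core macrophage, ribosomal, complement and interferon-stimulated genes lay lower there, and of all these lists only core macrophage genes passed with camera.

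Within the MHC-II-negative class, Retnla was 9.04-fold lower in melanophages (-3.18 ± 0.28, adjusted p = 0.00605) and was the only gene called. Within the MHC-II-positive class, melanophages had less Cd207 (-2.00 ± 0.21, adjusted p = 0.0192), read as a lower bound because their mean of 3.17 lay near the array medians, 2.71-fold less Itgax (-1.44 ± 0.16, adjusted p = 0.0229) and 2.62-fold less Slc2a1 (-1.39 ± 0.15, adjusted p = 0.0192). Camera called 6 lists in the MHC-II-negative class, of which 1 passed with an estimated correlation. Lysosomal genes (adjusted p = 0.00301, and adjusted p = 0.507 with an estimated correlation) and genes of lipid-associated macrophages (adjusted p = 0.00125, and adjusted p = 0.17 with an estimated correlation) were higher in melanophages there, with 2 and 2 genes higher and 1 and 0 lower adjusted over the list alone, and the sort markers were lower (adjusted p = 7.29e-08, and adjusted p = 0.00926 with an estimated correlation). In the MHC-II-positive class it called 10 lists, of which 0 passed with an estimated correlation, among them dendritic cell genes (adjusted p = 0.000176, and adjusted p = 0.0624 with an estimated correlation) (lower) and cell cycle genes (adjusted p = 0.0036, and adjusted p = 0.246 with an estimated correlation) (higher). The interaction of cell kind and MHC-II class did not pass for Retnla (1.37 ± 0.39), Cd207, Itgax or Slc2a1 (-1.04 ± 0.21). No gene had an interaction adjusted p under 0.966. Across all genes the differences in the MHC-II classes correlated with r = 0.28 (rho = 0.16), where genes are not independent replicates. The call of Retnla ended without MHC-II-negative melanophages replicate 1 (adjusted p = 0.0647), MHC-II-negative macrophages replicate 2 (0.0678) or MHC-II-negative macrophages replicate 3 (0.068), and the count was 8 and 2 without MHC-II-positive melanophages replicates 1 and 2, 4 without MHC-II-negative melanophages replicate 2, and 3 and 2 without MHC-II-positive macrophages replicates 2 and 3. In the MHC-II-positive class the count was 0 without MHC-II-negative melanophages replicate 1, MHC-II-negative macrophages replicate 1 or 2, or MHC-II-positive melanophages replicate 2 or 3. It was 5 without MHC-II-positive melanophages replicate 1, 5 and 1 without MHC-II-negative melanophages replicates 2 and 3, and 2, 6 and 20 without MHC-II-positive macrophages replicates 1, 2 and 3. The calls of Cd207 and Itgax also ended without MHC-II-positive melanophages replicate 1 (adjusted p = 0.0553 and 0.0613) and without MHC-II-negative melanophages replicate 3 (0.0537 and 0.061). Those of Cd207 and Slc2a1 ended without MHC-II-positive macrophages replicate 1 (0.0623 and 0.0527), and all 3 calls ended with quantile normalization again (0.061 each). In a fit of the arrays of the 2 groups alone 0 genes were called in either class with limma, where Retnla had an adjusted p of 0.108 and Cd207, Itgax and Slc2a1 of 0.31.

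The chemokine Ccl17 was 38.2-fold higher in MHC-II-positive than in MHC-II-negative cells, averaged over cell kind (log2 difference 5.26 ± 0.40 SE, adjusted p = 0.000111), rising from 3.68 ± 0.26 to 8.21 ± 0.36 in melanophages and from 4.66 ± 1.32 to 10.63 ± 0.73 in macrophages (SD, n = 3). Ccr2, a chemokine receptor of monocytes whose protein was absent by the sort gate, was 9.40-fold higher (3.23 ± 0.20, adjusted p = 3.93e-05). The prostaglandin synthase Ptgs2 was 6.44-fold higher (2.69 ± 0.20, adjusted p = 9.83e-05), and the inflammatory cytokine Il1b was 2.95-fold higher (1.56 ± 0.11, adjusted p = 9.83e-05). The scavenger receptor Colec12 was 2.56-fold lower (-1.36 ± 0.22, adjusted p = 0.0192).

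**Figure D2:**
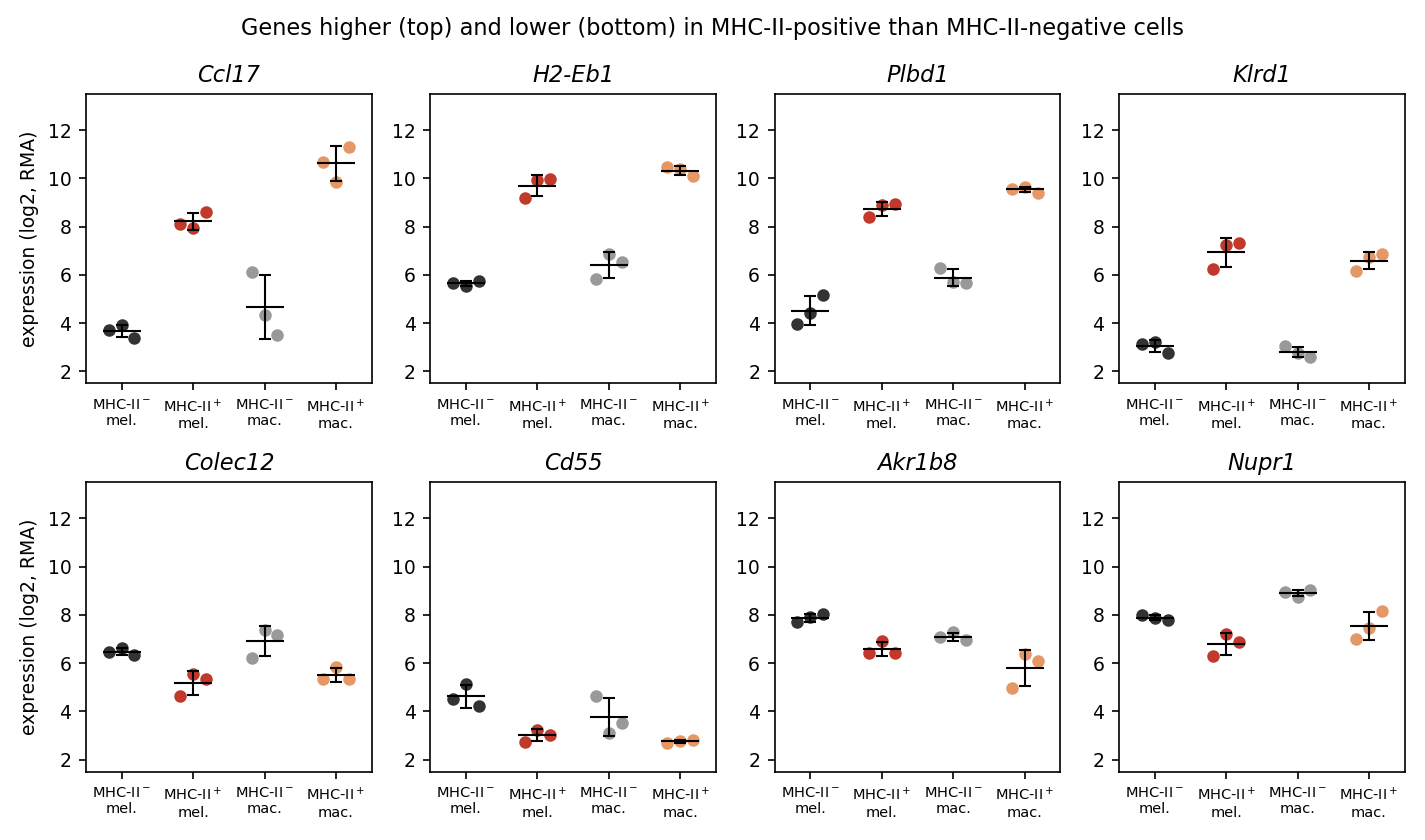
Expression (log2, RMA) of the 4 leading rises (top) and 4 leading falls (bottom) by the rule for named genes in MHC-II-positive against MHC-II-negative cells, in melanophages (mel.) and macrophages (mac.). Points are single arrays (n = 3 per group), long bars group means and error bars SD; Ccl17 averaged 3.68 in MHC-II-negative and 8.21 in MHC-II-positive melanophages.

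Averaged over cell kind, 152 genes differed, 126 higher and 26 lower in MHC-II-positive cells. At least 2-fold differences made up 76 of the rises and 6 of the falls. Quantile normalization again gave 119 higher and 47 lower, a smaller share of rises, and array weights gave 161 and 54. The MHC-II genes were among the largest rises, which follows from the sort and is no independent finding, with H2-Eb1 at 3.99 ± 0.18, H2-Aa at 3.32 ± 0.24 and H2-Ab1 at 2.81 ± 0.22. Next to them stood the invariant chain Cd74 (3.65 ± 0.29), the phospholipase-like Plbd1 (3.94 ± 0.19), the lectin-like receptor Klrd1 known from natural killer cells (3.84 ± 0.20), the apolipoprotein Apod (3.56 ± 0.67), Cytip (3.18 ± 0.27) and Mmp12 (2.95 ± 0.22). Among genes whose arrays did not overlap in either cell kind, the largest falls after Colec12 were those of the complement inhibitor Cd55 (-1.31 ± 0.24), the aldo-keto reductase Akr1b8 (-1.29 ± 0.21), the stress-induced Nupr1 (-1.22 ± 0.19), and Cnrip1 (-1.04 ± 0.15). They were followed by Ifitm6 (-0.99 ± 0.19), Dnm1 (-0.97 ± 0.17), B3galnt1 (-0.95 ± 0.16), the carbonyl reductase Cbr3 (-0.80 ± 0.13) and Rassf8 (-0.79 ± 0.13). An unadjusted p under 0.05 was found for 1840 genes, where chance gives 997. Arrays of the classes did not overlap, in the same direction in both cell kinds, for 221 genes higher and 152 lower, where chance gives 0.25% of genes (49.8) per direction.

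Of the 41 named calls of this comparison, 25 passed in all 24 alternatives, and 34 of the 41 in the fit of every probe set. Among the 10 largest rises Apod did not (adjusted p up to 0.12), and each of the 10 leading falls missed the threshold in some alternative, from Cnrip1 (adjusted p up to 0.0517) to Rassf8 (up to 0.189). Rassf8 has 2 probe sets, and its log2 difference ranged from -0.869 to -0.37 over the 24 alternatives. The mean of all probe sets of a gene ended 1 of the 41 named calls. Without MHC-II-negative melanophages replicate 3 the count fell from 152 to 96. The count of falls (26) was 43 without MHC-II-negative macrophages replicate 1, 11 and 12 without MHC-II-negative melanophages replicates 1 and 3, and 17 without MHC-II-positive macrophages replicate 1. It was 14 without MHC-II-positive melanophages replicate 2, MHC-II-positive melanophages replicate 3 or MHC-II-negative macrophages replicate 3.

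Of the 14 measured genes of MHC class II antigen presentation, 7 rose, 0 fell and 7 did not pass, with 9 higher adjusted over the list alone (adjusted p = 1.96e-22, and adjusted p = 0.000567 with an estimated correlation). Besides the MHC-II chains and Cd74 these were H2-DMa, which loads peptides (2.23), the co-stimulatory receptor Cd40 (0.97) and the thiol reductase Ifi30 (0.56). Of the 7 sort markers, Ccr2 and the 3 MHC-II chains rose, and 7 were higher adjusted over the list alone (adjusted p = 1.96e-22, and adjusted p = 0.000228 with an estimated correlation). The sort fixed the rise of the 3 chains in both lists. Without them the sort markers had a camera adjusted p of 7.8e-09 (0.00473 with an estimated correlation) and the presentation genes 8.16e-12 (0.00473). Genes that may vary together with the chains, such as Cd74 and H2-DMa, stay in, so these values are not independent of the sort. The other sort markers did not pass, with Cd24a at 1.54 ± 0.32 (adjusted p = 0.0679), Itgam at 0.63 ± 0.18 (adjusted p = 0.219) and Fcgr1 at 0.40 ± 0.16 (adjusted p = 0.447). Of 17 dendritic cell genes, 3 rose, 0 fell and 14 did not pass. The rises were those of the lymph node homing receptor Ccr7 (1.97 ± 0.27), Itgax (1.26 ± 0.11) and Cd207 (1.20 ± 0.15), with 5 higher adjusted over the list alone (adjusted p = 8.05e-08, and adjusted p = 0.00906 with an estimated correlation). The rise of Cd207 was read as a lower bound, since only its mean in MHC-II-positive macrophages lay clear of the array medians. Of 13 monocyte genes, Ccr2, Lyz1 (1.16 ± 0.15) and F10 (0.74 ± 0.11) rose, 0 fell and 10 did not pass, with 3 higher adjusted over the list alone (adjusted p = 0.000371, and adjusted p = 0.0199 with an estimated correlation). The median of the monocyte list was 0.02, and its mean 0.52.

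Of 17 genes of glycolysis and hypoxia, the glucose transporter Slc2a1 (1.25 ± 0.10), the growth factor Vegfa (1.16 ± 0.18) and the lactate transporter Slc16a3 (0.65 ± 0.11) rose, 0 fell and 14 did not pass, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 2.51e-06, and adjusted p = 0.0112 with an estimated correlation). Of 16 genes of lipid-associated macrophages only Itgax rose, and 6 were higher and 2 lower adjusted over the list alone (adjusted p = 0.000127, and adjusted p = 0.032 with an estimated correlation). Of 26 inflammatory cytokines and NF-kB targets, 5 rose, 0 fell and 21 did not pass, with 13 higher and 1 lower adjusted over the list alone (adjusted p = 7.48e-13, and adjusted p = 0.0846 with an estimated correlation). These were Ptgs2, Il1b, the anti-inflammatory cytokine Il10 (1.08 ± 0.19), the inflammasome sensor Nlrp3 (1.06 ± 0.12) and the interleukin receptor antagonist Il1rn (0.65). Of 11 genes of T cells and ILC, Il7r (1.94 ± 0.25) and Cd2 (1.37 ± 0.13) rose, with 2 higher adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.0846 with an estimated correlation). Of 15 core macrophage genes Aif1 rose (0.45 ± 0.08), with 3 higher adjusted over the list alone (adjusted p = 0.00585, and adjusted p = 0.173 with an estimated correlation).

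Camera called 14 lists in this comparison, 13 higher and 1 lower, and 6 of them passed with an estimated correlation, 2 of which hold the MHC-II chains of the sort. In 4 lists higher as a set 0 genes passed with limma, either over all genes or adjusted over the list alone, with 4, 5, 2 and 1 genes at unadjusted p under 0.05. These were, in that order, interferon-stimulated genes (adjusted p = 0.00108, and adjusted p = 0.183 with an estimated correlation), cell cycle (adjusted p = 0.0207, and adjusted p = 0.243 with an estimated correlation), cholesterol synthesis (adjusted p = 0.0243, and adjusted p = 0.268 with an estimated correlation) and ribosomal proteins (adjusted p = 0.0393, and adjusted p = 0.351 with an estimated correlation). The 11 mast cell genes were lower as a set with 0 passing with limma over all genes or over the list alone (3 with unadjusted p under 0.05; adjusted p = 0.00585, and adjusted p = 0.327 with an estimated correlation). Members of lists that did not pass included the lectin Clec7a, a receptor for fungal glucans, which rose (2.20 ± 0.25), and Colec12 in the scavenger list (adjusted p = 0.232). The lysosomal protease Ctsh rose (1.10 ± 0.15; list adjusted p = 0.31), as did the cystine transporter Slc7a11 (1.09 ± 0.13; NRF2 list adjusted p = 0.471) and the lectin Mgl2 (1.33 ± 0.26; resident list adjusted p = 0.0597). The endothelin receptor Ednrb fell (-1.22 ± 0.19; melanocyte list adjusted p = 0.289). Cholesterol efflux (0.289), iron handling (0.173), complement (0.216), immediate early genes (0.43), keratinocytes (0.941), hair follicle (0.356), fibroblasts (0.471), endothelium (0.478), B cells (0.478), neutrophils (0.941), Schwann cells (0.42), skeletal muscle (0.941) and pericytes (0.941) did not pass. Adjusted over the list alone, 4 scavenger genes were higher and 2 lower, 3 resident genes higher and 5 lower, and 3 lysosomal genes higher and 1 lower. Median and mean differed in sign for the lysosome, keratinocyte and neutrophil lists.

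Leaving out single arrays changed list calls between the MHC-II classes too. The call of cholesterol synthesis ended in 10 of 21 alternatives, among them the fits without MHC-II-positive melanophages replicate 1 (adjusted p = 0.0669), MHC-II-negative macrophages replicate 1 (0.0694), MHC-II-negative melanophages replicate 2 (0.0853), MHC-II-positive macrophages replicate 2 (0.0985) or MHC-II-negative macrophages replicate 3 (0.0865). That of ribosomal proteins ended in 9, among them those without MHC-II-positive melanophages replicate 1 (0.076), MHC-II-positive macrophages replicate 1 (0.129), MHC-II-negative macrophages replicate 2 (0.167) or MHC-II-negative melanophages replicate 3 (0.229). That of cell cycle genes ended in 7, among them those without MHC-II-positive macrophages replicate 1 (0.105), MHC-II-negative melanophages replicate 2 (0.0628) or MHC-II-negative macrophages replicate 2 (0.069). T cells and ILC lost their call without MHC-II-positive macrophages replicate 1 (0.0567). Core macrophage genes lost theirs in the brighter 50% of genes (0.067), above the 60th percentile (0.119) and with cyclic loess (0.0523), and interferon-stimulated genes above the 60th percentile (0.0863). The resident list, with an adjusted p of 0.0597, was called in 9 of 21 alternatives. Among these were the fits without MHC-II-negative macrophages replicate 1 (0.000217), MHC-II-positive melanophages replicate 2 (0.0264), MHC-II-positive macrophages replicate 2 (0.0373) or MHC-II-negative melanophages replicate 3 (0.0354). Iron handling was called without MHC-II-negative macrophages replicate 1 (0.0168) or MHC-II-positive melanophages replicate 2 (0.0497), and the lysosome list without MHC-II-negative macrophages replicate 3 (0.0478).

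Within melanophages 42 genes differed between the MHC-II classes (40 higher, 2 lower), and within macrophages 68 did (62 higher, 6 lower). The largest rises within melanophages were those of Ccl17 (4.54 ± 0.56), Plbd1 (4.23 ± 0.27), Cd74 (4.17 ± 0.41), H2-Eb1 (4.05 ± 0.26) and Klrd1 (3.89 ± 0.28). The falls there were those of Ednrb (-1.65 ± 0.27, adjusted p = 0.0489) and Pdc (-0.78 ± 0.11). Within macrophages the largest rises were those of Ccl17 (5.97 ± 0.56), H2-Eb1 (3.92 ± 0.26), Klrd1 (3.79 ± 0.28), Cytip (3.70 ± 0.39) and Plbd1 (3.65 ± 0.27). Falls there included Lgalsl (-1.18 ± 0.14), Prelp (-0.85 ± 0.12), Pdc (-0.79 ± 0.11), Pex13 (-0.63 ± 0.09) and Fbxo30 (-0.53 ± 0.09). In both kinds 27 genes were called, all 27 in the same direction, where independent lists would share 0.12 rises. That figure is too low as a baseline, because both comparisons share 1 estimate of spread per gene. The 27 also hold the MHC-II chains H2-Eb1, H2-Aa and H2-Ab1, whose rise in both kinds was fixed by the sort. All 42 genes called in melanophages had the same sign in macrophages, as had 64 of the 68 in the reverse comparison. Across all genes, which are not independent replicates, the differences in the cell kinds correlated with r = 0.47 (rho = 0.19). Camera called 8 lists in melanophages, of which 3 passed with an estimated correlation, and 12 in macrophages, of which 6 did. Quantile normalization again gave 73 higher and 20 lower genes in macrophages, array weights 77 and 24. The falls in macrophages (6) were 27 without MHC-II-negative macrophages replicate 1, 10 without MHC-II-positive melanophages replicate 1 and 3 without MHC-II-negative macrophages replicate 3. The count in melanophages was 19 without MHC-II-positive melanophages replicate 2 and 24 without MHC-II-negative melanophages replicate 3. Without the latter the call of Ccl17 in melanophages ended (adjusted p = 0.0566), and without MHC-II-negative macrophages replicate 2 that of H2-Ab1 in macrophages did (adjusted p = 0.0505).

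A fit of the arrays of the 2 groups alone, not among the 24 alternatives for single genes, kept all 10 named calls in melanophages. In macrophages it called 27 genes and kept 7 of 13 named calls, losing Ccl17 (adjusted p = 0.0696) and the 5 named falls (Lgalsl 0.079, the others from 0.141 to 0.347). Of the named falls within a cell kind, Lgalsl in macrophages passed in all 24 alternatives and the others did not. The fall of Ednrb in melanophages missed the threshold in 9 of the 12 leave-one-out fits and 3 other alternatives (adjusted p up to 0.192), and that of Pdc in melanophages in 5 and 1 (up to 0.0976). In macrophages Fbxo30 missed it in 11 and 6 (up to 0.151), Pex13 in 3 and 1 (up to 0.228), Prelp in 2 and 0 (up to 0.072) and Pdc in 2 and 0 (up to 0.0534). Pdc in melanophages missed it without MHC-II-negative melanophages replicates 1 and 3 or any of the 3 MHC-II-positive melanophage arrays. Among the leave-one-out fits Ednrb passed only without MHC-II-negative macrophages replicates 1 and 3 and MHC-II-positive macrophages replicate 1, and Fbxo30 only without MHC-II-positive macrophages replicate 3. Prelp, Pex13 and Pdc in macrophages missed it without MHC-II-positive macrophages replicate 2, Prelp and Pex13 also without replicate 1 of that group, Pex13 without MHC-II-negative macrophages replicate 3 and Pdc without MHC-II-negative macrophages replicate 2.

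**Figure D3:**
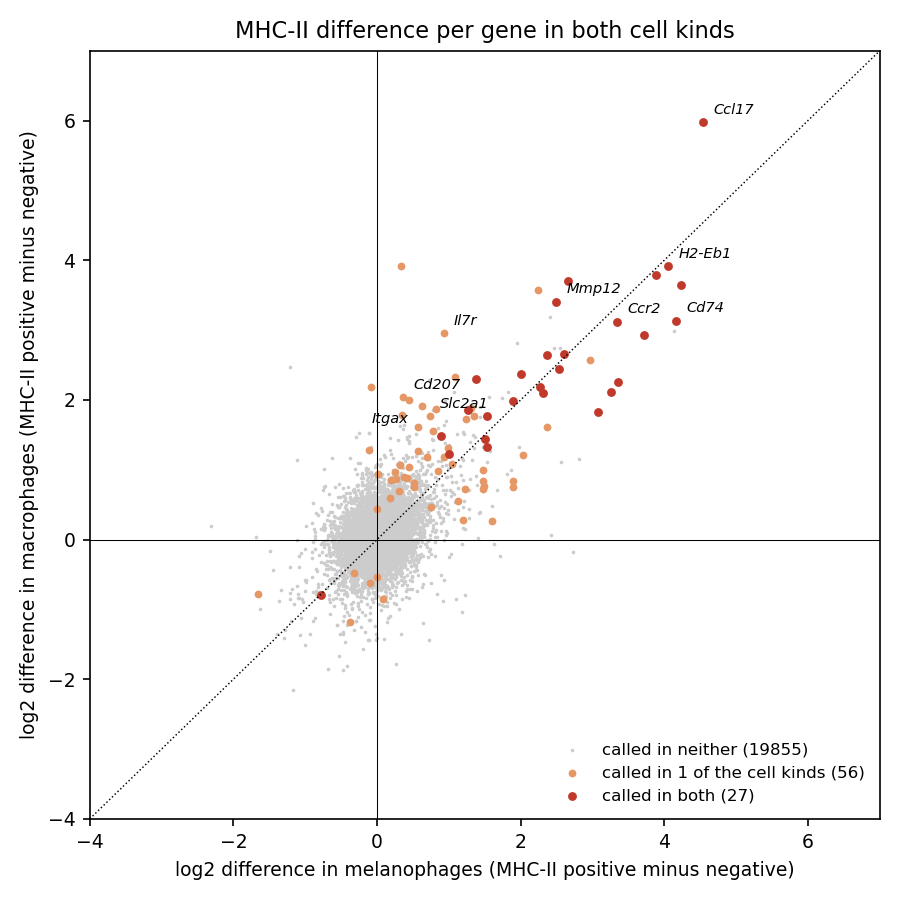
Log2 difference between MHC-II-positive and MHC-II-negative cells in melanophages (horizontal axis) and in macrophages (vertical axis), 1 point per gene, with equal differences on the dotted line. The 27 genes called in both cell kinds are red, 56 called in 1 cell kind orange and 19855 called in neither grey.

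The test of whether the MHC-II difference itself differed between the cell kinds called 0 genes with limma. An unadjusted p under 0.05 was found for 820 genes, where chance gives 997. The smallest adjusted p belonged to Itgax (-1.28 ± 0.23, adjusted p = 0.966) and Cd207 (-1.68 ± 0.30, adjusted p = 0.966), chosen after their values were seen. Cd207 averaged 2.81 ± 0.13 and 3.17 ± 0.22 in MHC-II-negative and MHC-II-positive melanophages and 3.13 ± 0.18 and 5.17 ± 0.48 in the corresponding macrophages (SD, n = 3). All but the last of these means lay near the array medians, so the size of its interaction is uncertain. With 0 genes called, differences between the cell kinds in what passed within each kind are not shown by the interaction test for any gene. The count was 1 without MHC-II-positive macrophages replicate 1 and 3 without MHC-II-positive macrophages replicate 2.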

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

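Tests of dendritic cells as the larger part of the gate, of monocytes, of a general lysosomal rise, of melanocyte RNA and of both far macrophage arrays together were chosen after the results were seen.

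The MHC-II difference was smaller in melanophages than in macrophages for 4 gene lists when the interaction was tested with camera, by mean log2 differences of -0.23 for lysosomal genes, -0.209 for lipid-associated macrophage genes, -0.275 for glycolysis and hypoxia and -0.27 for dendritic cell genes. None of these passed with an estimated correlation (adjusted p = 0.688, 0.354, 0.354 and 0.354). Among the 13767 probe sets without a single gene symbol, which entered no comparison, 25 differed between MHC-II classes when every probe set of the table was tested.

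Ccr2, Ccr7, Itgax and Cd207 were higher in MHC-II-positive cells of a gate described as CCR2-negative, CD24-negative and CD64-positive. Dendritic cells as the larger part of these cells are argued against by the mean difference of 8 macrophage genes (Adgre1, Mertk, Fcgr1, Cd14, C1qa, C1qb, C1qc and Mrc1). It was 0.0651 (95% bounds -0.0487 to 0.179), where a larger part was set to need a loss of 1. Fcgr1 counts little here, since it encodes CD64, for which all groups were gated. Mertk was less bright, with group means of 4.23 to 4.5. Adgre1, C1qa, C1qb, C1qc and Mrc1 differed by 0.105, -0.135, 0.0692, -0.13 and -0.0348, and Cd14 by 0.5. A minor part of dendritic cells stays open, since Flt3 and Zbtb46 differed by 0.257 on average (bounds -0.00257 to 0.517), with group means between 3.18 and 3.64. Monocytes as a minor part cannot be told apart from a change within macrophages either, because Plac8, Hp, Vcan and Chil3 differed by 0.365 on average (bounds -0.0826 to 0.813) and 3 of the 4 were dim, while the gate was Ly6C-negative. That mean came from Chil3 (1.59 ± 0.61 SE), while the dim Plac8 (-0.0424), Hp (-0.108) and Vcan (0.0183) hardly differed. The difference of Chil3 was read as a lower bound, since its means of 3.19 and 3.34 in MHC-II-negative melanophages and macrophages lay near the array medians. Higher expression of these genes in MHC-II-positive macrophages themselves may account for the pattern as well, and was not tested.

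Fewer genes were called between melanophages and macrophages (24) than between MHC-II classes (152). Leaving out MHC-II-negative macrophages replicate 1, the array farthest from its group mates, gave 19, short of a doubling. Each such fit uses fewer arrays, and the 12 leave-one-out fits gave 1 to 30 genes. The count of 19 therefore does not decide what that array contributed. Array weights gave 45, short of a doubling, so that unequal quality of the arrays cannot be told apart from other causes. Without that array and MHC-II-positive macrophages replicate 3 together 117 genes were called, against at most 30 without any other pair of arrays from different groups. Both comparisons have the same SE per gene, and its median was 0.0832 with all arrays and 0.0851 without these. The latter rests on fewer arrays, and at an unchanged spread their loss would have raised the SE by more than this. The spread of the median gene was therefore narrower without these arrays, as leaving out the farthest arrays tends to make it in any data. How much of the gain came from this spread, and how much from shifted group means, cannot be told apart. A smaller difference between the cell kinds as the reason for the lower count was not tested.

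Ctsk, Atp6v0d2 and Gpnmb were higher in melanophages. The other 32 lysosomal genes differed by 0.00669 on average (95% bounds -0.203 to 0.217), which argues against a general rise as their cause; in the MHC-II-negative class, where camera called the list higher (adjusted p = 0.00301, and adjusted p = 0.507 with an estimated correlation), it was 0.11 (-0.187 to 0.408), and averaged over the classes the list was called without MHC-II-negative melanophages replicate 2 (0.047) or MHC-II-negative macrophages replicate 3 (0.0156). Melanocyte RNA as their cause is argued against by Pmel, Tyr, Tyrp1, Dct and Mlana, which differed by 0.115 on average (bounds 0.0379 to 0.193), where it was set to need 1, though with group means of 2.23 to 3.41 near the floor a trace of it stays open. The lowest difference of the 3 genes over the 12 leave-one-out fits was 1.84, so no single array made up most of it. Leaving out 1 of 3 arrays moves a difference averaged over both classes little, so this was a weak test. The calls did depend on single arrays, since Gpnmb missed the threshold in 11, Atp6v0d2 in 9 and Ctsk in 2 of the 12 fits. Regulation of these genes by pigment uptake may be the cause but was not tested; expression in macrophages before and after they take up melanin would test it.

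Other splits of the arrays were counted for each comparison. For both averaged comparisons, of 100 splits drawn from 200 possible ones, only 1, the real split, gave as many genes. It gave 24 genes between the cell kinds against at most 1 in another split, and 152 between MHC-II classes against at most 6. This argues against a chance split of these arrays. It does not reach beyond them, since no label says that the arrays of a group came from separate animals. Within a class or kind the 10 splits are too few for a share under 0.05; the real counts of 1, 3, 42 and 68 stood against highest others of 0, 2, 1 and 1. For the interaction the real count of 0 is reached by all 100 splits whatever they hold (highest other 21), so this count decides nothing.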

How the results depend on the processing

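The tests without the 2 farthest macrophage arrays, of named genes in the fits of every probe set and of 2 groups only, of lists without the MHC-II chains, and of list means by run, were chosen after the result was seen. No result reversed. The cause of the changes was not tested, except that leaving out dim genes tests fewer genes and leaving out arrays uses fewer. For melanophages against macrophages averaged over MHC-II (24 genes), the count was 38 in the brighter 50% of genes and 38 above the 60th percentile in 3 arrays, 1 with every probe set, 45 with array weights, 12 with the sample-code run as a random block, and 117 without the 2 farthest arrays. In the MHC-II-negative class (1 gene) it was 7 above the 60th percentile, 2 with quantile normalization again, 2 with every probe set, 5 with limma trend, 0 with the arrays of the 2 groups only, 6 with the run as a replicate block, and 12 without the 2 farthest arrays. In the MHC-II-positive class (3 genes) it was 5 in the brighter 50%, 6 above the 60th percentile, 0 with quantile normalization again, 5 with every probe set, 8 with trend, 6 with array weights, 0 with 2 groups only and 34 without the 2 farthest arrays. The MHC-II comparison in macrophages (68 genes) gave 27 with 2 groups only. The called lists went from 7 to 1 with an estimated correlation and 1 with fry between cell kinds, and from 14 to 6 and 9 between MHC-II classes. Leaving out single arrays gave ranges of 1 to 30, 0 to 8 and 0 to 20 for these cell kind comparisons, 96 to 158 for MHC-II averaged, 19 to 46 in melanophages, and 0 to 3 for the interaction; called lists between cell kinds ranged from 5 to 13. In the other alternatives MHC-II averaged gave 135 to 215. No background or detection value was used, so a dim gene is not told apart from a silent one. An arm left with fewer arrays is assumed to vary like the other groups. Over all genes same-run arrays did not deviate together as a rule (18 pairs, correlations -0.248 to 0.27, median -0.0262, 5 above 0.1), so the main setting did not pair samples by run. Some list means did: all 4 groups deviated in the same direction in 23 of 96 combinations of list and run, against a median of 12 over 216 ways to match the arrays, of which 9, the real one included, gave at least as many. Interferon-stimulated genes did so in all 3 runs, as at least 1 list did in 44 of the 216 matchings. Resident macrophage genes, NRF2 targets and 3 lists of other cell types did so in 2. An effect shared by a run is therefore not excluded for these lists. The run as a fixed block gave 6 genes in the MHC-II-negative class and moved no other count by over 1.5 times, but it ended named calls. Of 21 between the cell kinds it kept 11 (as a random block 10), losing Gstm1, Naa20, Clec4d, Gstm3, Ccr1, Adgre5, Cx3cr1, Mmp12, Syngr2 and Cd207 (adjusted p from 0.0501 to 0.125). Of the 3 in the MHC-II-positive class it kept Itgax and lost Cd207 (0.0609) and Slc2a1 (0.0529), and of 41 between MHC-II classes it kept 35 (as a random block 37).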

Other observations

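Gene families by symbol stem and the genes named here were chosen after the results were seen.

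Among the genes higher in MHC-II-positive cells, the symbol stems Clec and Ccl were more frequent than among all 19938 genes. This baseline holds dim genes, while 6 of the 152 called genes were dimmer than the median gene. It therefore favours families expressed in these cells, and the test takes their members as independent. The stems do not hold all C-type lectins or chemokines. Of 33 genes with the stem Clec, 4 rose where the share over all genes gives 0.209 (Fisher's exact test, adjusted p = 0.0124 over 230 families). They were Clec7a (2.20 ± 0.25), Clec4b1 (1.99 ± 0.24), Clec4e, a receptor for mycobacterial glycolipid (1.93 ± 0.18), and Clec12a (1.19 ± 0.21). Of 19 genes with the stem Ccl, 3 rose where the share over all genes gives 0.12 (Fisher's exact test, adjusted p = 0.0255). They were Ccl17, Ccl22, which shares its receptor with Ccl17 (2.19 ± 0.14), and Ccl6 (0.74 ± 0.12). The difference of Ccl22 was read as a lower bound, since its means of 3.01 and 3.00 in the MHC-II-negative groups lay near the array medians. Neither family as a whole passed with camera and an estimated correlation (unadjusted p = 0.112 and 0.24).

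Without the far macrophage arrays, 117 genes differed between the cell kinds. Of the genes gained, Klra3 (2.30), Il7r (1.21), Cyba, a subunit of the phagocyte oxidase (1.07), Fabp5, a fatty acid binding protein (0.99), and Lgals3 (0.42) were higher in melanophages. Piezo1, a mechanosensitive channel (-1.57), Sema4a (-1.55), Itgav (-1.29), Egfr (-1.21), Runx3 (-1.18), Egr2 (-0.99) and Nr4a1 (-1.20) were lower. Of 22 immediate early and heat shock genes 4 fell there (camera adjusted p = 1.16e-14, and adjusted p = 0.0864 with an estimated correlation). Because these arrays were left out after the counts were seen, these adjusted p-values are too favourable and the genes are leads for a new experiment.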
